A study of Sus scrofa with 15 samples.

How the data were processed

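RNA sequencing of total RNA from the pig intestinal epithelial cell line IPEC-J2 gave 15 libraries in 5 groups of 3, per the labels. The authors deposited FPKM values per gene with 2 decimals, per the file headers, in one table for the 9 knockdown libraries and another for the 6 overexpression libraries. The submitters' processing notes name the genome build Sscrofa11.1. The aligner, the counting tool, the annotation version, strand use and any step between counts and FPKM are not given in the sources used here. The tables identify genes by NCBI Gene numbers and by identifiers of predicted genes. Symbols and 1-based coordinates were taken from a RefSeq gene table of the same build. A symbol was found for 18618 of 19000 genes in the knockdown table and 16949 of 17001 in the overexpression table, and 16804 genes are in both. All columns of per-sample values were used. The tables were normalised separately, so tests were made only within a table, and levels set across tables carry that limit.

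The groups are those of the sample labels. The design text gives miR-133 as the target of both knockdown vectors, while the sample labels call one of them Lv143KD. The label was followed, and a reader should hold the target of Lv143KD as unsettled. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. No pair of libraries held identical values.

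FPKM does not keep the read total. The spacing of low values was compared between libraries: over 15 to 23 genes per library the overexpression table gave steps of similar median size (median log2 ratios from 0 to 0.11, with only 39.1% to 58.8% of the genes within 0.2 of an equal step), while the knockdown table offered only 4 to 9 genes and left relative depth undecided. Precision is therefore given as the SD over 3 libraries and as the standard error of the fit, with a median standard error of 0.14 without and 0.10 with the block in the knockdown table, and of 0.13 and 0.11 in the overexpression table, on the log2 scale.

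Values were analysed as log2(FPKM + 1), which understates the change of low genes. Genes with at least 1 FPKM in at least 3 libraries of a table were tested, 11645 and 11506. Each table was fitted as a whole with limma 3.58.1 in R 4.3.3, with a trended empirical Bayes variance, two-sided tests and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 4 comparisons were Lv133KD and Lv143KD against Lv3NC, Lv133KD against Lv143KD, and OV143 against Lv20NC. The groups, the comparisons, the fit, the lists of genes and the rule for naming genes were chosen before the data were examined. Library weights, settings combined with the block, and most tests of explanations were added after.

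Libraries carry replicate numbers 1 to 3 in each group. Deviations from the group means of libraries with the same number correlated at 0.27 to 0.85 over the 9 pairs of the knockdown table and at 0.23 to 0.72 over the 3 pairs of the overexpression table, all above the limit of 0.1 set for pairing, against -0.87 to 0.38 and -0.68 to 0.54 for different numbers. Deviations within a group cancel out, so positive correlations of some pairs force negative ones of others. The contrast with different numbers is therefore no separate support. The pairing rests on this check, since the labels do not say what a number marks, and Lv133KD replicate 3 resembled Lv143KD replicate 1 most. The fit with the replicate number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times.

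Named genes were those passing the threshold with all 3 treated libraries above or all below the 3 controls (the 10 largest changes each way), up to 4 passing members of a described list, the 5 genes with the smallest p where fewer than 10 passed, and literature targets of each miRNA. Results of some genes that this rule names are not reported here. The same rule was applied to the fit with the block, with a common direction in the 3 pairs in place of separated groups for falls such as that of MT-2B, an extension chosen after the data were seen. The 35 lists of genes hold 813 symbols, of which 768 were found. The 33 lists with at least 5 tested members in each table were tested with camera, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the lists of a comparison. Endothelial markers had 4 and 3 members that passed the filter and mitochondrially encoded genes 0, so neither was tested.

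Shared controls were simulated with 100 draws of unchanged groups, the controls included, made from mixtures of the residuals. The scheme was tested on simulated data with 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold. The changed genes were drawn only from those averaging above about 5 FPKM, and noise was drawn independently for each gene and library. The rates below therefore do not cover lower genes or deviations that genes of a library share. Without the block the fit recovered 29.9%, 83.6% and 97.0% of them for Lv133KD, 34.3%, 77.6% and 100% for Lv143KD, and 34.3%, 85.1% and 100% for OV143. With the block it recovered 94.0% of the 67 genes changed by 1.5-fold for Lv133KD, 85.1% for Lv143KD and 76.1% for OV143. Unchanged genes were called too, 10 of 150 calls for Lv133KD, 17 of 158 for Lv143KD and 7 of 153 for OV143 without the block. With the block these were 8 of 204, 16 of 206 and 6 of 190, and 17 of 211 for Lv133KD against Lv143KD. Alternatives were another pseudocount, no filter and a stricter filter, size factors by median of ratios, the block, each library left out, a fold minimum, fits on a pair of groups, library weights, and combinations with the block. A test of miRNA seed sites in 3′ UTRs was planned but not run, since no genome sequence or UTR annotation was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.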

Results

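Gene expression was measured by RNA sequencing in IPEC-J2 cells, a non-transformed epithelial cell line derived from the jejunum of a newborn pig, carrying lentiviral vectors directed at the microRNAs miR-133 or miR-143. The 15 libraries form 5 groups of 3. The knockdown table holds the control vector Lv3NC, the miR-133 knockdown Lv133KD and the vector labelled Lv143KD, 9 libraries in all. The overexpression table holds the control vector Lv20NC and the miR-143 overexpression vector OV143, 6 libraries in all. The design text and the sample labels differ on which miRNA the Lv143KD vector targets, and the sample label is used throughout. No miRNA has an entry in either table, so the levels of miR-133 and miR-143 in these libraries are not known here and the action of each vector on its miRNA was not checked.

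The knockdown table lists 19000 genes, of which 11645 were tested, and the overexpression table lists 17001, of which 11506 were tested. Between 11250 and 11557 genes reached 1 FPKM in each library. Read totals are not recoverable from FPKM, so the depth of the libraries is unknown; the FPKM sums were 486086 to 520631 in the knockdown table and 518578 to 558042 in the overexpression table, apart from 662022 in OV143 replicate 2. The cells had an epithelial profile in both tables, with the keratin gene KRT8 at 741.2 ± 128.7 FPKM over the 9 knockdown-table libraries (SD) and the adhesion gene EPCAM at 300.5 ± 28.8 FPKM. The leukocyte gene PTPRC is listed at 0 in every library of the knockdown table.

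The libraries did not separate by vector in the knockdown table. Its first principal component held 61.8% of the variance and set the 3 libraries numbered 2 (-18.4 to -22.9) apart from Lv143KD replicate 3 (28.2) and Lv3NC replicate 3 (32.0). In the overexpression table the first component held 68.7% and set OV143 replicate 2 (39.6) apart from the other 5 libraries. Libraries with the same replicate number tended to deviate together, so results of a fit with the replicate number as a block are given beside those without it. The pairing was not clear-cut in the overexpression table. There the deviations of Lv20NC replicate 3 correlated at 0.55 with OV143 replicate 3 and at 0.54 with OV143 replicate 1. Those of Lv20NC replicate 1 and OV143 replicate 1 correlated at 0.23.

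**Figure D1:**
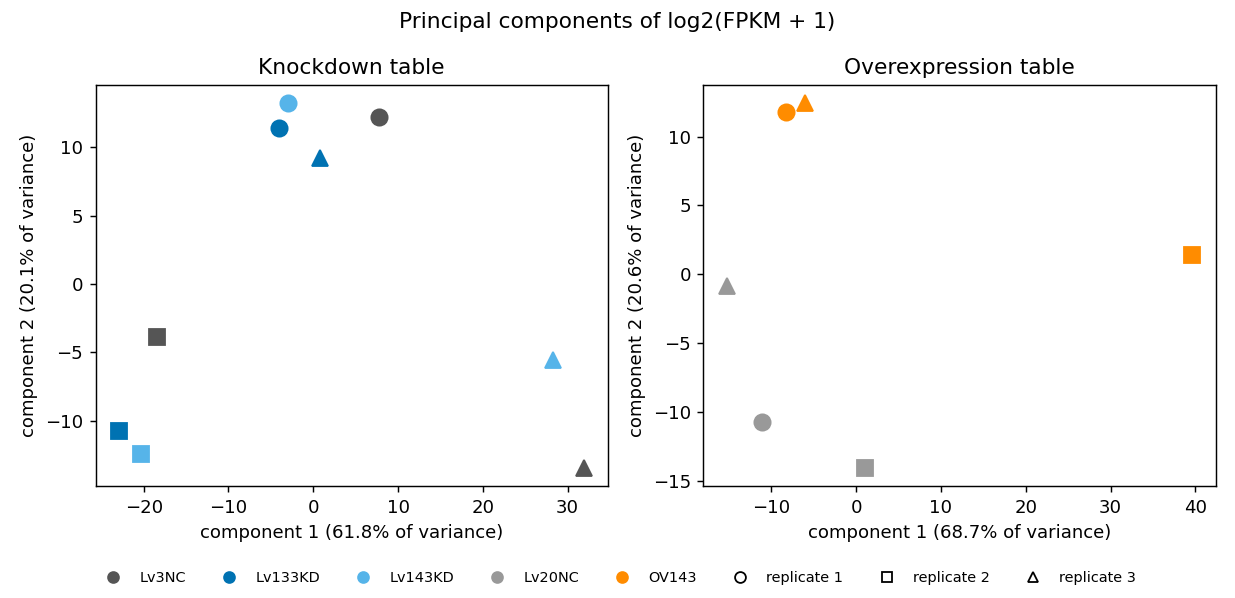
Principal component scores (unitless, log2 scale) of the 9 libraries of the knockdown table and of the 6 libraries of the overexpression table; each point is one library, coloured by group and numbered by replicate. The libraries numbered 2 lie at -18.4 to -22.9 on the first axis of the knockdown table, and OV143 replicate 2 lies at 39.6 on the first axis of the overexpression table.

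The first comparison asked which genes differ when miR-133 is knocked down. In Lv133KD, FOPNL and ATP6V1H rose against Lv3NC. FOPNL (NCBI Gene 100621608), which encodes a centrosomal protein and lies on chromosome 3 from 6977195 to 6996024 of Sscrofa11.1, was at 10.7 ± 1.12 FPKM in Lv133KD and 4.06 ± 0.581 FPKM in Lv3NC (SD, n = 3 each; log2 fold change 1.21, SE 0.13, limma adjusted p = 0.0331). ATP6V1H (NCBI Gene 397472; chromosome 4 from 77211493 to 77269757), a subunit of the vacuolar proton pump, was at 46.2 ± 0.802 FPKM against 26.9 ± 1.78 FPKM (log2 fold change 0.76, SE 0.08, adjusted p = 0.0331). The next 3 genes by p did not pass. WIF1, a secreted WNT inhibitor, was at 7.26 ± 0.998 against 2.87 ± 0.514 FPKM (adjusted p = 0.0840). AACS, which activates acetoacetate for lipid synthesis, was at 9.67 ± 0.0889 against 3.96 ± 0.870 FPKM (adjusted p = 0.0840), and ALG5, an enzyme of N-glycan assembly, was at 50.8 ± 3.37 against 28.1 ± 4.04 FPKM (adjusted p = 0.147).

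With the replicate number as a block, 30 genes passed in Lv133KD, 29 higher and 1 lower, by 1.40-fold to 2.32-fold. The largest rises after FOPNL were those of AACS (log2 fold change 1.12), the lysosomal galactosidase GLA (1.11), WIF1 (1.10), the clathrin adaptor subunit AP1M1 (0.99) and the guanylate cyclase subunit GUCY1A3 (0.85), followed by ALG5 (0.84), the biliverdin reductase BLVRA (0.80), the RNA-binding protein HNRNPAB (0.79) and LRRC1 (0.77). The gene that fell was the metallothionein MT-2B, at 540.5 ± 228.2 FPKM against 811.6 ± 289.6 FPKM. It was lower in each of the 3 pairs, its log2 fold change was -0.62 (adjusted p = 0.0172 with the block, 0.926 without). Reads of metallothioneins can be shared between near-identical copies. Among the lists of genes, XPO5, which exports precursor miRNAs from the nucleus, rose in the miRNA biogenesis list (68.1 ± 4.94 against 40.1 ± 7.44 FPKM, log2 fold change 0.76, adjusted p = 0.00837 with the block and 0.290 without). The sterol enzyme gene HSD17B7 rose by 0.57 on the log2 scale with the block.

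Several groups of genes shifted together in Lv133KD by small amounts, by camera with its preset correlation. Of 22 genes of cholesterol biosynthesis, 18 were higher (median log2 fold change 0.28, adjusted p = 5.63e-05). HSD17B7 was the 1 member that passed singly, with the block, and also the 1 that rose when adjusted over the list alone. Of 30 genes of G1/S transition and DNA replication, 26 were higher (median 0.37, adjusted p = 0.00106), with none passing singly over all genes and 1 rising with the block when adjusted over the list alone. Of 40 ribosomal protein genes, 38 were lower (median -0.12, adjusted p = 2.49e-07), none singly. Lower as groups were also extracellular matrix and integrins (29 genes, median -0.12, adjusted p = 0.00155) and antigen presentation by MHC class I (16 genes, -0.14, 0.00409). So were the ATF4 amino acid response (23 genes, -0.34, 0.0140) and tight and adherens junctions (21 genes, -0.11, 0.0172), as well as mitotic genes of G2/M (30 genes, -0.11, 0.0181) and immune cell markers (6 genes, -0.19, 0.0214, and 0.0963 with the block), with no member of these passing singly. The miRNA biogenesis list was higher (13 genes, median 0.13, adjusted p = 0.0292). The p53 target list was lower only with the block (19 genes, median -0.15, adjusted p = 0.00735, and 0.0746 without). Adjusted over the list alone with the block, 9 ATF4 genes and 3 p53 targets fell and 2 miRNA biogenesis genes rose. None of these lists passed with an estimated correlation. Adjusted p was 0.517 for cholesterol biosynthesis, 0.872 for G1/S and 0.743 for ribosomal proteins. It lay between 0.517 and 0.881 over the 10 lists called without the block, and at least 0.809 with it. The calls of cholesterol biosynthesis (medians from 0.16 to 0.39) and ribosomal proteins (-0.19 to -0.05) held without any 1 library, but the ribosomal call was lost with the block without the libraries numbered 3 (adjusted p = 0.725). The G1/S and extracellular matrix calls were lost without Lv3NC replicate 3 (adjusted p = 0.358 and 0.313). The ATF4 call was lost without Lv3NC replicate 1, Lv3NC replicate 3 or Lv133KD replicate 2 (up to 0.895), and the MHC class I call without Lv3NC replicate 3 or Lv133KD replicate 3 (up to 0.0911). The miRNA biogenesis call was lost without Lv3NC replicate 2, Lv3NC replicate 3 or Lv133KD replicate 2 (up to 0.154), and that of junctions without Lv3NC replicate 2, Lv133KD replicate 1 or Lv133KD replicate 3 (up to 0.336). The call of immune markers was lost without Lv3NC replicate 2, Lv3NC replicate 3 or Lv133KD replicate 3 (up to 0.361), and that of G2/M without Lv3NC replicate 2, Lv3NC replicate 3, Lv133KD replicate 1 or Lv133KD replicate 3 (up to 0.399). With the block and without the libraries numbered 3, the G2/M list passed in the other direction (median 0.0406, camera adjusted p = 0.0240).

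In Lv133KD, 380 genes had an unadjusted p under 0.05 without the block and 1922 with it, where chance gives 582, and 8.02% of genes had separated groups, where chance gives 10%. Leaving out any 1 of the 6 libraries ended the calls of FOPNL and ATP6V1H (smallest adjusted p of any gene between 0.0542 and 0.364), and with the block 0, 14 and 72 genes passed without the libraries numbered 1, 2 and 3.

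The same question was asked of the Lv143KD vector. FOPNL was at 10.7 ± 1.08 FPKM in Lv143KD (log2 fold change 1.21, SE 0.13, adjusted p = 0.0338) and ATP6V1H at 46.4 ± 0.182 FPKM (0.77, SE 0.08, adjusted p = 0.0338). No other gene passed. WIF1 (7.12 ± 0.701 FPKM, adjusted p = 0.110), AACS (8.92 ± 1.29 FPKM, adjusted p = 0.177) and the FAS-associated factor FAF1 (17.6 ± 1.72 against 9.90 ± 0.559 FPKM, adjusted p = 0.177) followed by p without passing. With the block, 20 genes passed, by 1.39-fold to 2.73-fold, and the largest change was a rise of a gene not named here. Of these 20 genes, 18 were higher and 2 lower. They included WIF1 (log2 fold change 1.07), AACS (1.01), GLA (0.91), GUCY1A3 (0.77), FAF1 (0.77), ALG5 (0.74), XPO5 (0.65, adjusted p = 0.0280) and the N-terminal acetyltransferase subunit NAA15 (0.63). The genes that fell were MT-2B (547.7 ± 213.0 against 811.6 ± 289.6 FPKM, log2 fold change -0.58, adjusted p = 0.0339 with the block) and LOC100519675, a gene without a proper name that was picked out after its values were seen (11.5 against 20.9 FPKM, log2 fold change -0.80, adjusted p = 0.0363 with the block).

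**Figure D2:**
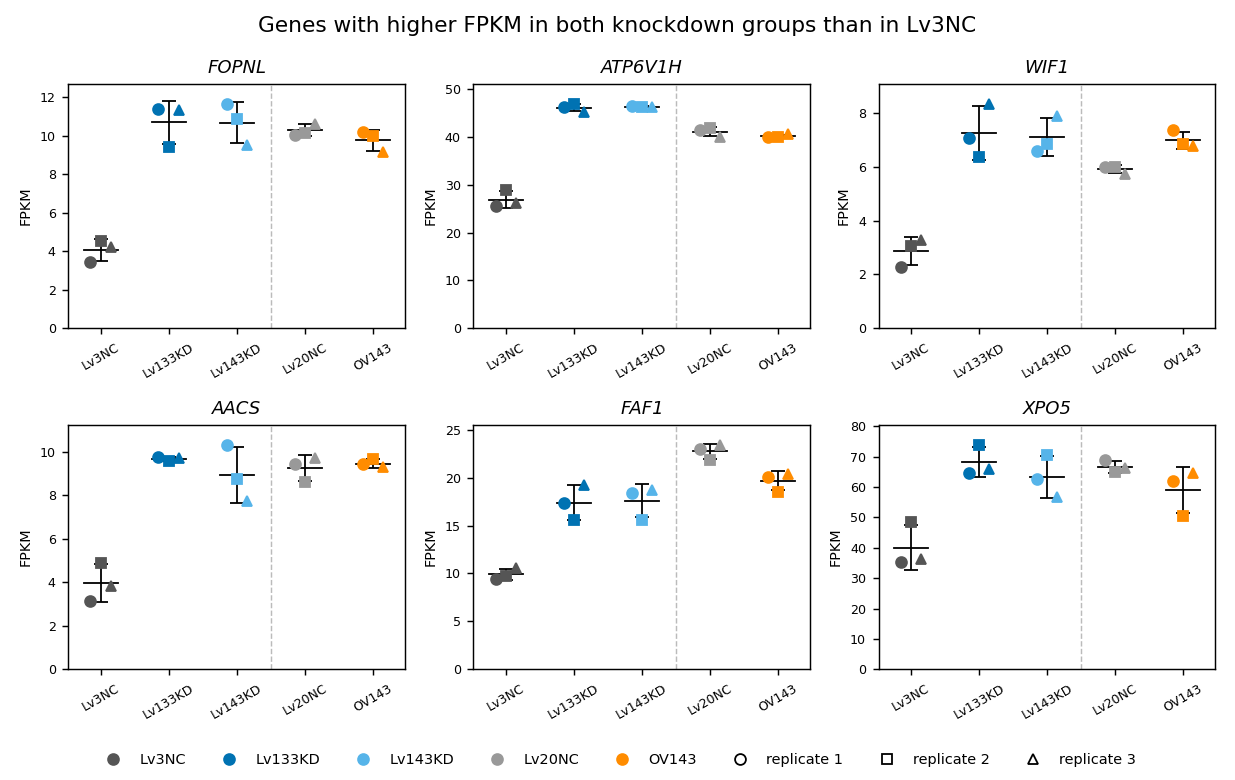
FPKM of FOPNL, ATP6V1H, WIF1, AACS, FAF1 and XPO5 in the 5 groups; horizontal lines are means of 3 libraries, error bars their SD, points the single libraries, and the dashed line parts tables that were normalised separately. FOPNL averaged 4.06 FPKM in Lv3NC and 10.7 FPKM in Lv133KD.

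By gene group, 38 of 40 ribosomal protein genes were lower in Lv143KD (median log2 fold change -0.08, camera adjusted p = 6.03e-05), as was MHC class I presentation (14 of 16 genes, median -0.09, adjusted p = 0.0346), while 10 of 13 miRNA biogenesis genes were higher (median 0.03, adjusted p = 0.0346), 2 of them when adjusted over the list alone. With the block, 3 further lists passed. The ATF4 amino acid response was lower in 22 of 23 genes (median -0.18, adjusted p = 2.43e-06, and 0.117 without the block). The p53 targets were lower in 16 of 19 genes (median -0.11, 0.00551, and 0.117 without), and interferon-stimulated genes were higher in 22 of 26 (median 0.09, 0.0126, and 0.104 without). In the fit without the block, leaving out 1 library moved the ATF4 median between -0.50 and 0.20 and the p53 median between -0.24 and 0.00542. The interferon median moved between -0.16, without Lv143KD replicate 1, and 0.20. With an estimated correlation the lists that passed with the preset correlation had an adjusted p = 0.922, and those that passed with the block an adjusted p = 0.947. Apart from XPO5 no member of these lists passed singly over all genes. Lv143KD had 208 genes with an unadjusted p under 0.05 without the block and 669 with it, where chance gives 582, and 4.14% of genes had separated groups, where chance gives 10%. The ribosomal call was lost without Lv3NC replicate 2, Lv3NC replicate 3 or Lv143KD replicate 1 (up to 0.993). The miRNA biogenesis call was lost without Lv3NC replicate 2, Lv3NC replicate 3, Lv143KD replicate 1 or Lv143KD replicate 3 (up to 0.464), and the MHC class I call without any 1 of the libraries other than Lv3NC replicate 1 (up to 0.765). Leaving out any 1 of the 6 libraries ended the calls of FOPNL and ATP6V1H without the block, and with the block 1, 3 and 60 genes passed without the libraries numbered 1, 2 and 3.

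The remaining lists did not pass in Lv133KD or Lv143KD, with the block or without. They included the literature targets of miR-143 (median log2 fold change -0.01 in Lv133KD and 0.05 in Lv143KD over 19 genes) and of miR-133 (medians of -0.0035 and -0.04 over 24 genes); in Lv133KD both had means above 0 (0.02 and 0.01) and test directions below it. Single targets described in the literature did not pass either. In Lv133KD the log2 fold changes were 0.29 for the actin-bundling protein FSCN1, -0.16 for EGFR, -0.07 for CDC42 and -0.02 for RHOA. In Lv143KD they were 0.18 for the hexokinase HK2, 0.10 for FSCN1 and 0.07 for MAPK7.

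Calls in both knockdowns were compared next. FOPNL and ATP6V1H were called in both, where independent lists of 2 genes would share 3.43e-04 higher genes. With the block 19 genes were called in both, 18 higher against an expected 0.0448 and MT-2B lower against an expected 1.72e-04. Unchanged groups simulated against shared controls shared no call in 100 draws of either fit. The controls were simulated too, so shared calls that come from the real Lv3NC values were not covered. Across genes, which are not independent replicates, the fold changes correlated at r = 0.77 (rho = 0.75), while the simulated unchanged groups had a median r of 0.69. Leaving out 1 library moved r between 0.22 (without Lv143KD replicate 2) and 0.93 (without Lv3NC replicate 2), and the covariance between 0.00578 and 0.0551. The covariance was 0.0185, against a simulated mean of 0.0217 (range of the middle 95%: -0.0171 to 0.0945) without the block and 0.00603 (-0.00648 to 0.0219) with it. The 3 controls cannot be divided into groups of 2, so part of the excess of shared calls may come from the shared controls.

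The direct comparison of Lv133KD with Lv143KD, which leaves the controls out of the contrast, gave no gene with limma, with the block or without; 15 genes had an unadjusted p under 0.05 without the block and 209 with it, where chance gives 582, and the smallest adjusted p were 1.00 and 0.910. By p without the block SLC2A2 came first (log2 fold change -1.02, 115.6 ± 35.2 FPKM in Lv133KD against 239.7 ± 103.1 in Lv143KD). HOXB13 (0.26), C12H17orf58 (0.25), PRRG2 (-0.33) and NSMF (0.21) followed, and none of these genes passed. Groups of genes did differ by camera with its preset correlation. Cholesterol biosynthesis was higher in Lv133KD in 20 of 22 genes (median 0.24, adjusted p = 4.75e-09), with no library whose omission ended the call (medians from 0.12 to 0.36). G1/S genes were higher in 28 of 30 (median 0.35, adjusted p = 5.76e-07; 0.439 without Lv143KD replicate 3). Lower in Lv133KD were extracellular matrix and integrins (27 of 29 genes, median -0.09, 1.76e-06; 0.590 without Lv143KD replicate 3), G2/M genes (27 of 30, -0.09, 2.91e-06; 0.473 without Lv143KD replicate 2, and also lost without Lv133KD replicate 3), ribosomal proteins (33 of 40, -0.03, 0.00376; 0.752 without Lv143KD replicate 2, and also lost without Lv133KD replicate 3) and enterocyte differentiation (8 of 13, -0.07, 0.00766; 0.150 without Lv143KD replicate 2). The enterocyte list holds SLC2A2, whose change was far larger than the median of the list, so its call need not reflect the list as a whole. The ATF4 list was lower with the block alone (median -0.07, adjusted p = 0.00144, and 0.110 without). Without Lv143KD replicate 3 or Lv133KD replicate 2 it passed in the other direction in the fit without the block (medians 0.20 and 0.33, adjusted p = 0.0477 and 0.0363). With an estimated correlation the adjusted p was 0.361 for cholesterol biosynthesis, 0.668 for G1/S and at least 0.361 for the others, and 0.830 for each of the 7 lists with the block.

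The overexpression comparison asked which genes differ when miR-143 is raised. Without the block no gene passed in OV143 with limma, although 1304 genes had an unadjusted p under 0.05 (2288 with the block), where chance gives 575, and the groups were separated for 21.9% of genes, where chance gives 10%. The genes with the smallest p were the RING finger gene RNF39 (8.19 ± 0.454 FPKM in OV143 against 19.2 ± 1.60 in Lv20NC, SD, n = 3 each), the fructose transporter SLC2A5 (5.94 ± 0.150 against 2.62 ± 0.142 FPKM), the RNA-editing enzyme APOBEC1 (3.43 ± 0.358 against 7.69 ± 0.139 FPKM) and the interferon-induced IFIT3 (18.7 ± 2.69 against 7.70 ± 0.470 FPKM), each at an adjusted p = 0.0590, and the Fc receptor FCGR3A (35.4 ± 5.70 against 14.7 ± 1.11 FPKM, adjusted p = 0.0640).

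With the block 223 genes passed, 74 higher and 149 lower. The largest rise was that of ISG15 (NCBI Gene 100145895; chromosome 6 from 63363201 to 63364211), an interferon-induced ubiquitin-like protein, from 34.7 ± 4.01 to 125.7 ± 54.9 FPKM (log2 fold change 1.75, block adjusted p = 0.00209). It was followed by the vasodilator peptide gene ADM (1.28), the chemokine CCL5 (1.24; 106.5 ± 32.2 against 43.5 ± 6.20 FPKM), FCGR3A (1.20), IFIT3 (1.17) and SLC2A5 (0.94), and by S100A8 (0.88), ECM1 (0.87), S100A12 (0.84) and the retinoid-binding CRABP2 (0.83). FCGR3A and the S100 genes belong to families with close paralogs, whose reads the counting could have divided between copies. The largest fall was that of the macrophage growth factor CSF1 (NCBI Gene 100513084; chromosome 4 from 110178466 to 110198232), from 166.8 ± 36.2 to 58.0 ± 17.7 FPKM (log2 fold change -1.53, block adjusted p = 0.00803). TRIB3 (-1.45), SESN2 (-1.44), CHAC1 (-1.39), USP53 (-1.36), CDK5R1 (-1.23), the EGFR inhibitor ERRFI1 (-1.22), the EGFR ligand EREG (-1.20), PTGS2 (-1.16), the prostaglandin synthase also known as COX-2, and PLK3 (-1.15) followed.

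**Figure D3:**
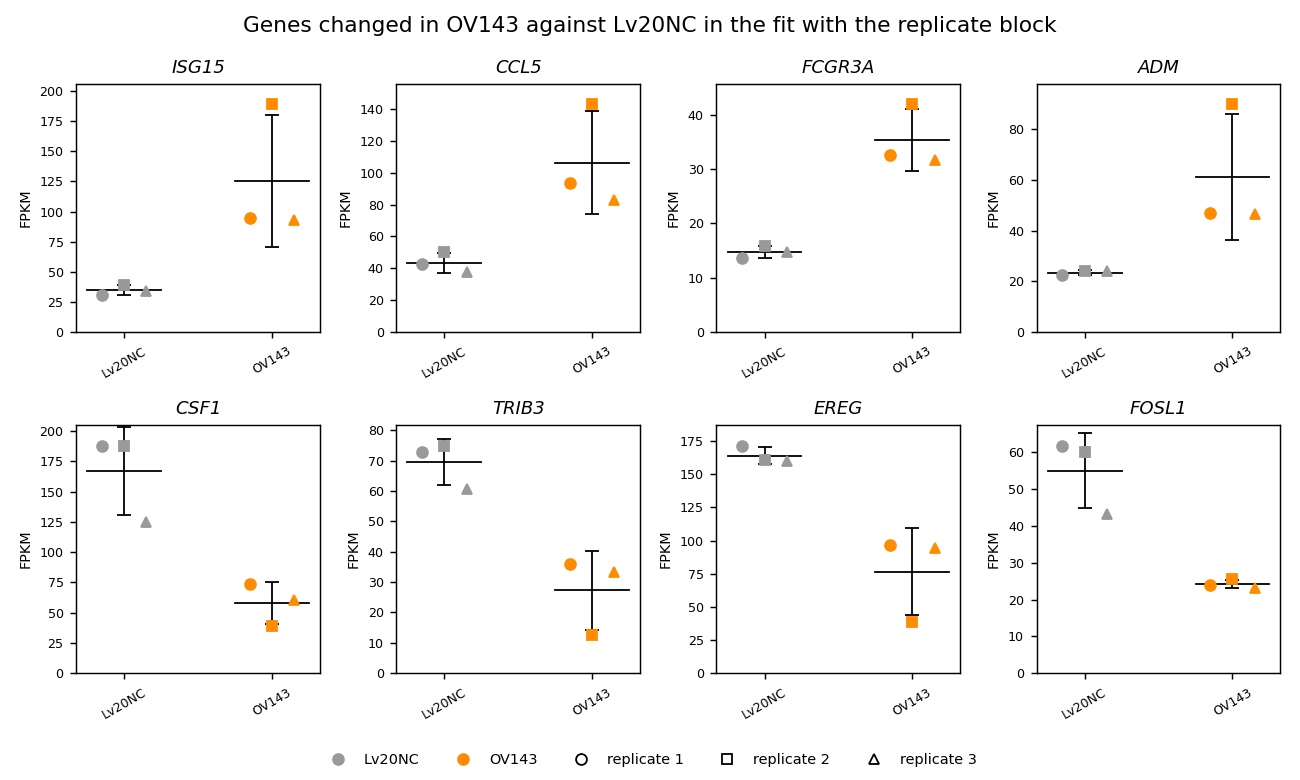
FPKM of ISG15, CCL5, FCGR3A, ADM, CSF1, TRIB3, EREG and FOSL1 in Lv20NC and OV143; horizontal lines are means of 3 libraries, error bars their SD and points the single libraries. ISG15 averaged 34.7 FPKM in Lv20NC and 125.7 FPKM in OV143, and CSF1 166.8 and 58.0 FPKM.

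Groups of genes that were higher in OV143 by camera with its preset correlation included mitotic genes, interferon-stimulated genes and hypoxia genes. All 30 G2/M genes were higher (median log2 fold change 0.30, adjusted p = 2.33e-13). With the block 4 rose, namely the anaphase activator CDC20 (0.62; 80.8 ± 23.7 against 50.8 ± 2.73 FPKM), the survivin gene BIRC5 (0.56), and KIF20A and NUSAP1 (both 0.52), and 22 rose when adjusted over the list alone. Of 28 interferon-stimulated genes, 24 were higher (median 0.30, adjusted p = 8.23e-10). With the block 5 rose, among them ISG15, IFIT3, IFI6 (0.78) and IFIT1 (0.74), and adjusted over the list alone 13 rose and 1 fell. Of 27 genes of hypoxia and glycolysis, 22 were higher (median 0.31, adjusted p = 6.40e-08; median 0.17 without OV143 replicate 2). ADM, ANKRD37 (0.82), the oxygen-sensing hydroxylase EGLN3 (0.80) and another 2 rose with the block, the angiogenic factor VEGFA fell (-0.63), and adjusted over the list alone 15 rose and 1 fell. Counts over the list alone are from the fit with the block. With an estimated correlation the adjusted p was 0.132, 0.132 and 0.355 for these 3 lists.

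Groups that were lower in OV143 were targets of growth factor, inflammatory and stress signalling. Of 26 MAPK feedback and immediate early genes, 23 were lower (median -0.40, adjusted p = 1.99e-10). Of these 7 fell with the block, among them the AP-1 subunit FOSL1 (-1.14; 24.2 ± 1.20 against 55.0 ± 10.3 FPKM), EGR3 (-1.01), PHLDA1 and the ephrin receptor EPHA2 (-0.99). Adjusted over the list alone 17 fell and 1 rose. Of 21 inflammatory cytokine and NF-kB genes, 19 were lower (median -0.43, adjusted p = 1.11e-08). Of these 6 fell with the block, among them the NF-kB inhibitor TNFAIP3 (-0.97), LIF (-0.82) and IL1A (-0.81), while CCL5 rose. Adjusted over the list alone 16 fell and 1 rose. Of 23 ATF4 amino acid response genes, 21 were lower (median -0.40, adjusted p = 8.72e-07). Of these 5 fell with the block, among them TRIB3, SESN2, CHAC1 and the cystine transporter SLC7A11 (-1.14). Adjusted over the list alone 15 fell and 1 rose. Of 21 TGF-beta and YAP targets, 17 were lower (median -0.39, adjusted p = 3.19e-05). Of these 6 fell with the block, among them AMOTL2 (-1.06) and the tissue factor gene F3 (-0.99; 467.3 ± 95.5 against 917.6 ± 83.8 FPKM), while 3 rose, among them the BMP-responsive ID3 (0.60) and ID1 (0.52). Adjusted over the list alone 14 fell and 3 rose. Amino acid and peptide transporters were lower in 13 of 16 genes (median -0.40, adjusted p = 0.00265; median -0.19 without OV143 replicate 2), with SLC7A11 and the arginine transporter SLC7A1 (-0.88) falling with the block. With an estimated correlation the adjusted p was 0.321, 0.199, 0.395, 0.395 and 0.443 for these 5 lists. In the knockdown table such lists also differed between single libraries of the same vector. Mean deviations within Lv133KD ran from -0.94 to 0.31 (log2) for ATF4 genes and from -0.36 to 0.23 for MAPK feedback genes. Within Lv143KD those of inflammatory genes ran from -0.35 to 0.52. Single libraries thus differed by more than these medians without a change of vector.

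**Figure D4:**
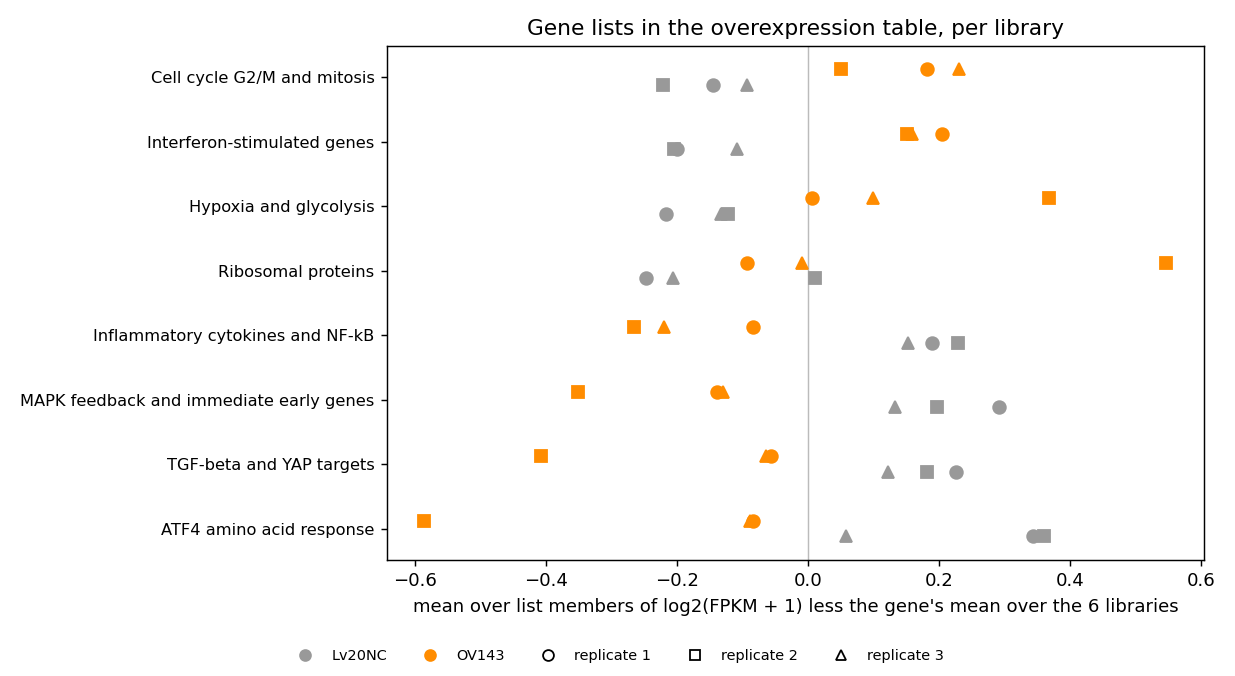
Mean deviation (log2) of 8 lists of genes in each library of the overexpression table from the mean over its 6 libraries; each point is one library, coloured by group. The G2/M list had a median log2 fold change of 0.30 and the MAPK feedback and immediate early list one of -0.40.

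Other lists shifted in OV143 too. All 40 ribosomal protein genes were higher (median 0.29, adjusted p = 2.05e-09; 0.446 with an estimated correlation), and none passed singly; the median was 0.09 without OV143 replicate 2, whose FPKM sum stood apart (adjusted p = 9.05e-04). ER stress genes (14 of 20, median 0.23, and 0.15 without that library, adjusted p = 0.00314) and MHC class I presentation (14 of 16, median 0.14, from 0.09 to 0.25 without 1 library, 0.00173) were also higher, with no member passing singly. The p53 targets were lower (12 of 19, median -0.16, from -0.27 to -0.12 without 1 library, 0.0272), and SESN2 and the apoptosis activator BBC3 (-0.75) fell with the block. Literature targets of miR-143 were lower in 17 of 19 genes (median -0.19, adjusted p = 0.00405), with PTGS2 among those that fell with the block, and 3 falling when adjusted over the list alone; without OV143 replicate 2 the median was -0.03 and the call was lost (adjusted p = 0.0845). The same library ended the calls of nuclear oxidative phosphorylation (18 of 20 higher, median 0.15, adjusted p = 0.00140; 0.176 without it), oxidative stress genes (15 of 18 higher, 0.15, 0.0106; 0.0995 without it; the 2 members that passed with the block, SLC7A11 and OSGIN1 at -0.63, fell) and immune cell markers (6 of 6 higher, 0.23, 0.00357; 0.0878 without it), of which the lymphocyte gene NKG7 rose with the block (0.53). Cholesterol biosynthesis was higher in 17 of 22 genes (median 0.09, adjusted p = 0.0184) and lost its call without Lv20NC replicate 2, OV143 replicate 2 or OV143 replicate 3 (highest adjusted p 0.137). With an estimated correlation the adjusted p of these 8 lists lay between 0.316 and 0.482.

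With the block alone, mucins and epithelial defence were higher in OV143 (7 of 9 genes, median 0.23, adjusted p = 0.0284, and 0.0613 without the block), with S100A8 and S100A9 (0.73) rising, and extracellular matrix and integrins were lower (22 of 29 genes, median -0.17, 0.0297, and 0.0586 without), with ITGA3 (-0.64) falling. In the fit without the block OV143 replicate 2 carried most of both shifts: without it the medians were 0.02 and -0.05 (adjusted p = 0.321 and 0.616). With an estimated correlation the adjusted p was 0.421 and 0.604. Lists that passed in neither fit still held genes that passed singly with the block. In enterocyte differentiation SLC2A5 and the brush-border peptidase ANPEP (0.81) rose and the transcription factor KLF4 (-1.07) fell. Of the miR-133 literature targets CTGF (-0.77) and SNAI1 (-0.96) fell, the latter also on the mesenchymal list, KRT80 (-0.95) fell among the keratins, and the chaperone HSPA6 (0.60) rose. The literature targets MAPK7 (log2 fold change -0.20), HK2 (-0.19) and FSCN1 (-0.07) of miR-143 did not pass singly.

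OV143 replicate 2 decided the count of single genes in the fit without the block. Without this library 511 genes passed, 150 higher and 361 lower, and they held 195 of the 223 genes called with the block; without any other single library none passed with limma, with 599 to 1326 genes at an unadjusted p under 0.05. With the block, 683, 1454 and 278 genes passed without the libraries numbered 1, 2 and 3, from 1 residual degree of freedom and a spread taken wholly from the trend over genes.

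Lv143KD and OV143, opposite vectors for miR-143 by their sample labels only, were compared last. Over the 11142 genes tested in both tables, the log2 fold changes of Lv143KD and OV143 correlated at r = -0.03 (rho = -0.06) across genes, which are not independent replicates, and an exact two-sided relabelling of the 6 overexpression libraries gave p = 0.9, where 10 splits allow no p under 0.1. Leaving out single libraries moved r between -0.31 and 0.11. Of 19 genes called with the block in Lv143KD and 216 in OV143, none was called in opposite directions, where independent lists would share 0.221 genes higher in Lv143KD and lower in OV143 and 0.0127 of the other kind; 1 was lower in both.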

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

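The tests in this part were chosen after the results were seen.

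FAF1 and XPO5 differed in opposite directions under Lv143KD and OV143, which are opposite vectors by their sample labels only. FAF1 was lower in every OV143 library than in every Lv20NC library (log2 fold change -0.20) and higher in every Lv143KD library than in every Lv3NC library (0.77). XPO5 was likewise lower in OV143 (-0.18) and higher in Lv143KD (0.65). Both genes came from a scan of the genes named for Lv143KD or OV143, and of the lists, for groups separated in opposite directions. Over all tested genes the groups were separated for 21.9% in OV143 and 4.14% in Lv143KD, in either direction. The difference between the vectors was not tested for either gene, and neither change in OV143 passed with limma. The rises were not particular to Lv143KD. FAF1 averaged 17.4 FPKM in Lv133KD and 17.6 in Lv143KD, against 9.90 in Lv3NC. XPO5 averaged 68.1 and 63.2 FPKM, against 40.1 in Lv3NC.

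Both genes belong to a set of 29 genes that rose with the block in at least 1 knockdown, of which 27 are in both tables. Over these 27 genes the median level was 0.69 higher (log2) in the knockdowns than in Lv3NC, and it was 0.73 higher in Lv20NC, a control vector with no knockdown, than in Lv3NC. OV143 was 0.69 higher too, and 25 of the 27 genes lay closer in Lv20NC to the knockdowns than to Lv3NC. Of 10000 expression-matched random lists, 0% had a median as large (their middle 95%: -0.09 to 0.21). The 27 genes were chosen for being higher than these Lv3NC libraries, and the random lists were not. That choice alone can place Lv20NC above Lv3NC, so the random lists cannot weigh an offset between the tables. Low values in the Lv3NC libraries, rather than raised values in both knockdowns, are a possible explanation that the deposit cannot settle. FOPNL averaged 4.06 FPKM in Lv3NC, 10.7 in both knockdowns, 10.3 in Lv20NC and 9.77 in OV143. The median lay at percentile 100 of the random lists, which do not share the choice of genes. An effect of the knockdowns stays open, also because the tables were normalised separately and may come from different experiments.

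Shared controls may bear on the same genes. The covariance of the fold changes of both knockdowns over all tested genes was 0.0185. It lies inside the middle 95% of 100 simulated pairs of unchanged groups without the block (-0.0171 to 0.0945) and with it (-0.00648 to 0.0219). These ranges are wide and cover all genes, so they cannot decide whether shared controls explain the called genes. No simulated pair shared a called gene, where the knockdowns shared 19 with the block. The controls of these pairs were simulated as unchanged too. The contrast therefore does not weigh shared calls that come from the real Lv3NC values.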

How the results depend on the processing

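Fits with library weights, the block combined with another setting, and the relation and shared calls with the block were chosen after the results were seen; the other alternatives were planned. The causes of changes were not tested, apart from fewer libraries or genes in the fit. Counts of called genes for Lv133KD, Lv143KD and OV143 were 2, 2 and 0, and moved as follows. No filter gave 1, 1 and 0, and size-factor scaling 1, 2 and 0. A fold minimum of 2 gave 1, 1 and 0. Fits on the 2 groups alone gave 0 for both knockdowns. Pseudocount 0.1 and the stricter filter changed no count. The replicate block gave 30, 20 and 223, with size-factor scaling 41, 29 and 232 (38 of 41, 27 of 29 and 89 of 232 higher), with pseudocount 0.1 30, 20 and 186, and library weights gave 205, 70 and 2650. The block without replicate 1 gave 0, 1 and 683, without replicate 2 14, 3 and 1454, and without replicate 3 72, 60 and 278. Leaving out 1 library gave 0 in every case for both knockdowns and 0 to 511 for OV143. Lv133KD against Lv143KD gave 0 in every setting run. Genes shared by both knockdowns numbered 2, and 1 with no filter, 1 with size-factor scaling, 19 with the replicate block and 0 with any 1 library left out.

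The relation of Lv143KD and OV143 (r = -0.03) ranged from -0.31 to 0.11 with 1 library left out and was -0.15 with the block without replicate 2. Directions of small changes that turned were as follows. RHOA in Lv133KD was 0.0454 with library weights and 0.0386 with the block without replicate 3. It ranged from -0.0750 to 0.0359 with 1 library left out. In Lv143KD, FSCN1 was -0.0421 with the block without replicate 1, and MAPK7 -0.0448 with the block without replicate 3. With 1 library left out HK2 ranged from -0.11 to 0.44 and MAPK7 from -0.24 to 0.35. In OV143, HK2 was 0.0259 with library weights. With 1 library left out HK2 ranged from -0.36 to 0.0635 and FSCN1 from -0.24 to 0.0232. Medians of lists turned with the block without replicate 3 for G2/M in Lv133KD (0.0406, which passed as higher, camera adjusted p = 0.0240). In that setting those of extracellular matrix (0.0186) and ribosomal proteins (0.0167) in Lv133KD against Lv143KD turned too. In the same setting the test turned for ribosomal proteins in Lv133KD (median -4.8e-05) and Lv143KD (-0.00892). With 1 library left out, medians in Lv133KD ranged from -0.22 to 0.0371 for G2/M and from -0.49 to 0.0645 for ATF4 genes. In Lv143KD they ranged from -0.16 to 0.20 for interferon-stimulated genes, -0.50 to 0.20 for ATF4 genes, -0.0321 to 0.12 for miRNA biogenesis and -0.24 to 0.00542 for p53 targets. In Lv133KD against Lv143KD they ranged from -0.0784 to 0.0230 for ribosomal proteins, 0.0117 to 0.48 for G1/S, -0.50 to 0.33 for ATF4 genes, -0.15 to 0.0115 for extracellular matrix and -0.0810 to 0.00425 for enterocyte differentiation.

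Over named genes, 1057 values under the alternatives kept direction and side of the threshold, 531 passed where they had not, 36 ceased to pass and 13 turned; over lists the counts were 608, 58, 110 and 13. The planned test of seed sites was not run for lack of 3′ UTRs.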

Other observations

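Of the tests in this part, the splits of the libraries without the block were planned, and the splits with the block, the tests of the OV143 genes and that of immune cells were chosen after the result was seen.

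The cell line had epithelial transcripts and part of the mesenchymal and enterocyte markers. In the knockdown table the junction genes CLDN4 (437.1 ± 155.9 FPKM, SD over 9 libraries), CLDN1 (399.7 ± 60.7), CDH1 (176.7 ± 8.72) and OCLN (76.4 ± 15.9) stood beside the intermediate filament gene VIM at 1307.9 ± 185.7 FPKM, with SNAI1 (17.7 FPKM), TWIST1 (4.24), COL1A1 (3.62) and ZEB1 (3.52) lower and ACTA2 (0.119), COL3A1 (0.03) and PDGFRA (0.00222) near 0. Of enterocyte genes the glucose transporter SLC2A2 stood at 163.8 ± 80.7 FPKM, KLF4 at 65.3 and the sucrase gene SI at 3.17. The regulator HNF4A was at 12.3 ± 0.824 FPKM and the peptidase DPP4 at 17.4 ± 2.56, while the intestinal regulator CDX2 (0.0178 FPKM), the lactase gene LCT (0.117) and the secreted mucin MUC2 (0.0189) were near 0. The membrane mucins stood higher, MUC4 at 71.9 ± 10.4 and MUC1 at 58.1 ± 16.8 FPKM. Among Toll-like receptors TLR3, a sensor of double-stranded RNA, stood at 21.8 ± 3.95 FPKM and TLR4, the lipopolysaccharide receptor, at 0.0311 FPKM, although its partner LY96 reached 26.1 ± 4.70. In the overexpression table TLR3 ranged from 0.24 to 11.8 FPKM over the 6 libraries.

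Libraries of the knockdown table differed within their groups in stress and cell cycle genes. The mean deviation of the 23 ATF4 amino acid response genes from the table mean was -0.94, -0.97 and -0.43 (log2) in the libraries numbered 2 of Lv133KD, Lv143KD and Lv3NC, and 0.24 to 0.58 in the other 6. Amino acid transporters followed, at -0.42, -0.46 and -0.23 in the libraries numbered 2. The 30 G1/S genes were at -0.69 in Lv143KD replicate 3 and -0.63 in Lv3NC replicate 3, and at -0.03 to 0.29 in the others, Lv133KD replicate 3 included. These values come with no explanation here, and the libraries were not grouped by them for any test.

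The 223 genes called in OV143 with the block were weighed against several explanations. OV143 replicate 2 as the whole cause is argued against, since 195 of them were also called without it in the fit with no block, where leaving out any 1 of the others kept 0. A single scaling factor per library as the whole cause is argued against too. Such a factor moves all genes the same way, and 74 of the 223 rose while 149 fell. These counts do not bear on a bias that acts on some genes only, such as one of transcript length, which was not tested. If the level of miR-143 were the cause, genes that fell in OV143 might rise in Lv143KD: the 145 measured there had a median log2 fold change of -0.0736, below the middle 95% of random lists (-0.04 to 4.6e-04), and 51 were above 0. The 71 genes that rose in OV143 were lower in Lv143KD as well (median -0.05, random lists -0.04 to 0.01, 26 above 0), so both sets shifted down. The random lists treat genes as independent, which genes that change together are not. The correlation of Lv143KD with OV143 across genes moved between -0.31 and 0.11 with 1 library left out. The target of the Lv143KD vector is unsettled and no miRNA was measured, so an action of miR-143 stays open.

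FCGR3A, a receptor of leukocytes, was 20.6 FPKM higher in OV143, which might point to immune cells among the cultures. The summed gain of TYROBP (1.78), AIF1 (2.89), CD68 (1.08), LYZ (0.193) and FCER1G (-0.177) was 5.76 FPKM, under that of FCGR3A alone; PTPRC was also chosen for this sum and is not listed in the overexpression table. NKG7 (0.53) and CCL5 (1.24, log2, with the block) rose too. The immune marker list was higher in 6 of 6 genes. Its mean deviation was 0.45 in OV143 replicate 2 and -0.00356 and -0.0120 in the other OV143 libraries, against -0.14, -0.08 and -0.22 in Lv20NC. All OV143 libraries thus lay above all controls, but most in replicate 2, and the call was lost without OV143 replicate 2. The sum assumes a profile of the cells, so immune cells stay open, and no biological explanation was tested.

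Splits of the 6 libraries of each comparison into groups of 3 were too few for a share under 0.05: 10 without the block and 4 that part the 3 pairs with it. These numbers, and the counts of splits below, include the real split itself. Of the 10, 1 gave as many genes as the real split for Lv133KD (2 genes; highest other 0), 2 for Lv143KD (2 genes; highest other 1857), and all 10 for OV143 and for Lv133KD against Lv143KD (0 genes; highest other 0). Of the 4, 1 gave as many for Lv133KD (30 genes; highest other 0), Lv143KD (20; 0) and OV143 (223; 0), and 4 for Lv133KD against Lv143KD (0; 0). The split with 1857 genes set Lv143KD replicate 3, Lv3NC replicate 1 and Lv3NC replicate 3 against Lv143KD replicates 1 and 2 and Lv3NC replicate 2, which points to a structure of the samples other than the vectors. The splits with the block part each pair of equal numbers, as the real one does, and differ in which member of a pair goes to which side.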
